A study of Homo sapiens with 8 samples.

How the data were processed

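RNA-seq was carried out on 8 LNCaP samples, 2 in each of 4 groups: DMSO, DHT, DHT with ENZ and DHT with ET516. Per the labels, RNA was extracted with TRIzol and libraries were made with a TruSeq RNA v2 kit, which does not mark the strand. The authors name FastQC, fastp, HISAT, featureCounts and DESeq2 and the build GRCh38, without versions and without saying what each was used for. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. The deposited table holds raw counts for 60279 genes in 8 columns, and these were used as deposited. Gene positions are from GENCODE v29 on GRCh38, joined by gene identifier for 17374 of the tested genes (98%).

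Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr on the 4 groups, which left 17737 genes, and libraries were scaled by TMM, with factors from 0.979 to 1.009. A quasi-likelihood model with robust=TRUE was fitted to all 8 libraries with 1 mean per group and 4 residual degrees of freedom. Each of 6 comparisons was tested as a contrast of that model, and a gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 4.3%. Levels are TMM-scaled CPM, and 95% intervals of fold changes are from the same model. The replicate numbers were not used as a block, since deviations from the group means correlated by only -0.033 to 0.035 between samples of the same number. With 14466453 to 20820192 counts per library, intervals of fold changes and list levels cover counting error and the spread between these samples only. The floor of 3 counts over a group is a fixed count and does not cover the spread between samples. Wilson intervals of shares of genes treat genes as independent and do not cover the spread between samples.

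In total, 24 gene lists were written from general knowledge before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives. The 20 lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, adjusted over those lists in each comparison. Camera with an estimated correlation and fry were the alternatives. Named genes are the 6 higher and 6 lower with the largest fold change per main comparison (mean of at least 5 CPM over the 8 libraries and no overlap between groups), up to 4 members of each list past the test, and KLK3, KLK2, TMPRSS2 and FKBP5. Some genes that the rule selects are left out of the text. Other genes were named after their values were seen: ATF5, HSPA1A, SLC2A3, KIF2C in the comparison of ET516 with DHT, the DUX4 family, and the examples of lists chosen later. Genes changed in 2 comparisons that share the DHT libraries were set against the number for independent lists and against 20 simulations of unchanged groups.

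The alternatives were DESeq2 1.42.0 and limma-voom, RLE and total-count scaling, no filter (at least 1 count) and a stricter one (1 CPM in 4 libraries), a fit to the compared groups alone, a replicate block, robust=FALSE, thinning to 14466453 counts, an adjusted p under 0.01, a 2-fold minimum, and leaving out each library in turn. The steps were tested on simulated data made from these libraries with 50 genes changed at each fold. In the simulation of DHT+ET516 against DHT, edgeR recovered 34%, 76%, 86% and 94% of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, with 12 false calls, and a simulation of DHT+ENZ against DHT without changes gave 6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.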

Results

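RNA was sequenced from LNCaP cells, an androgen-sensitive line derived from human prostate cancer. The 8 libraries formed 4 groups of 2: DMSO, DHT, DHT with ENZ, and DHT with ET516. The labels do not spell out DHT or ENZ, so both are written as given, and ET516 is a code name without a structure. The DHT dose is not given in the labels. Compounds were used at 10 µM for 12 h, with DHT added 2 h after the compound, in medium containing fetal bovine serum. Gene counts totalled 14466453 to 20820192 per library. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Counts of replicates differed by more than sampling noise in each group, with chi-square per degree of freedom from 2.08 in DHT+ENZ to 3.58 in DHT. The first principal component held 44.9% of the variance, with the DHT+ET516 libraries at 55.4 and 59.5 and the other 6 libraries between -29.1 and -9.9. The second held 15.1%, with the DHT libraries at -32.2 and -26.3 and the other 6 between -5.5 and 23.0. Mitochondrially encoded RNA took 4.76% ± 0.11 of the counts in DMSO, 5.01% ± 0.03 in DHT, 4.92% ± 0.01 in DHT+ENZ and 5.06% ± 0.18 in DHT+ET516 (mean ± SD, n = 2). Unless said otherwise, adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 17737 genes, and those of gene lists are from camera over 20 lists.

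The first comparison asked how the cells responded to DHT. DHT raised well-known androgen-induced genes. KLK3, which encodes prostate-specific antigen (ENSG00000142515, chromosome 19, 50854915 to 50860764, GRCh38), rose from 1970 ± 97 to 3480 ± 74 CPM (counts scaled to library size per 1e6, mean ± SD, n = 2), 1.76-fold. Its neighbour KLK2, another kallikrein protease (ENSG00000167751, chromosome 19, 50861568 to 50880567), rose 2.96-fold, from 170 ± 12 to 503 ± 7.7 CPM. The membrane protease gene TMPRSS2 (ENSG00000184012, chromosome 21, 41464551 to 41531116) rose 2.61-fold to 537 ± 3.6 CPM. FKBP5, a co-chaperone gene (ENSG00000096060, chromosome 6, 35573585 to 35728583), rose 3.95-fold to 630 ± 9.4 CPM. The adjusted p in edgeR was 2.61e-11 for KLK3 and 1.08e-22 or less for the other 3.

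Of the 43 measured members of the androgen-induced list, 37 rose, 1 fell and 5 did not pass with DHT, and adjusted over the list alone 39 rose and 1 fell. Their median log2 fold change was 0.98, with an adjusted p of 8.87e-05 in camera with an estimated correlation. Among genes with a mean of at least 5 CPM over the 8 libraries, the largest increases included the kinase gene SGK1 (log2 3.38 ± 0.22 SE, from 1.51 ± 0.21 to 15.7 ± 1.1 CPM) and the transcription factor gene MAF (3.33 ± 0.21). RHOU (2.28 ± 0.06), CDC42EP3 (2.24 ± 0.09) and EAF2, a transcription elongation factor gene (2.20 ± 0.14), followed. TRIM49D1 also rose (2.70 ± 0.19), but it has a near-identical copy and its counts are uncertain. Among the same genes, those that fell most were ACKR3, an atypical chemokine receptor gene (-1.5 ± 0.15), PLEKHS1 (-1.47 ± 0.16), the Wnt ligand gene WNT5A (-1.21 ± 0.19), OSR2 (-1.19 ± 0.13), SYTL2 (-1.15 ± 0.08) and MID1 (-1.03 ± 0.19).

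In the androgen-repressed list, 5 of 10 measured members fell with DHT, none rose and 5 did not pass, and adjusted over the list alone 6 fell. The members that fell included ACKR3, CAMK2N1 (-0.55), UGT2B15 (-0.65) and FOLH1, the gene of prostate-specific membrane antigen (-0.17). UGT2B15 has close paralogs whose reads the counting could have split. The list passed camera with the preset correlation (adjusted p = 6.73e-06) and with an estimated one (adjusted p = 0.0463).

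Genes of the unfolded protein response rose in 9 of 19 cases with DHT and none fell. Adjusted over the list alone 14 rose, and the median was 0.15 (camera adjusted p = 4.96e-10, and 0.0203 as adjusted p with an estimated correlation). They included ERN1, the gene of the endoplasmic reticulum stress sensor IRE1 (0.79 ± 0.06), the co-chaperone gene DNAJB9 (0.85 ± 0.09) and HSPA5, the gene of the chaperone BiP (0.26 ± 0.04). Of 17 fatty acid synthesis genes, 4 rose and 3 fell, and adjusted over the list alone 4 rose and 4 fell. The acyl-CoA ligase gene ACSL3, also a member of the androgen-induced list, rose (1.04 ± 0.04). The fatty acid elongase genes ELOVL5 (0.69 ± 0.04) and ELOVL7 (0.40 ± 0.05) rose as well. The fatty acid list had a median of -0.04, a mean of 0.08 and an upward camera call (adjusted p = 0.00341). That call was lost with an estimated correlation (adjusted p = 0.295). Of 5 aryl hydrocarbon receptor targets 2 rose, TIPARP by 1.04 and CYP1B1 by 0.42, and adjusted over the list alone 3 rose (camera adjusted p = 0.00529, and adjusted p = 0.161 with an estimated correlation). CYP1B1 lost its call without any 1 of the 4 DMSO and DHT libraries, with edgeR adjusted p from 0.0598 without DHT replicate 2 to 0.194 without DHT replicate 1, 0.121 without DMSO replicate 1 and 0.184 without DMSO replicate 2. Of 13 mitochondrially encoded mRNAs 4 rose, MT-CO2, MT-ND2, MT-ND4 and MT-ATP6, all by 0.16 or less, and adjusted over the list alone 6 rose. That call (camera adjusted p = 0.00529) was lost with an estimated correlation (adjusted p = 0.459), and without DMSO replicate 1 none of the 4 genes passed edgeR, with adjusted p of 0.366, 0.530, 0.486 and 0.541 in that order.

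The other 14 lists did not pass with DHT, and the basal, neuroendocrine, fibroblast and leukocyte lists had 4, 3, 4 and 2 measured members and were not tested in any comparison. In all, 1084 genes changed with DHT, 655 higher and 429 lower, of which 151 changed at least 2-fold. Without DMSO replicate 1 there were 693 (420 higher and 273 lower), and without DHT replicate 1 the number lower was 251. With total counts as the only scaling the split was 540 higher and 702 lower, which is 43.5% higher against 60.4% in the main result.

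**Figure D1:**
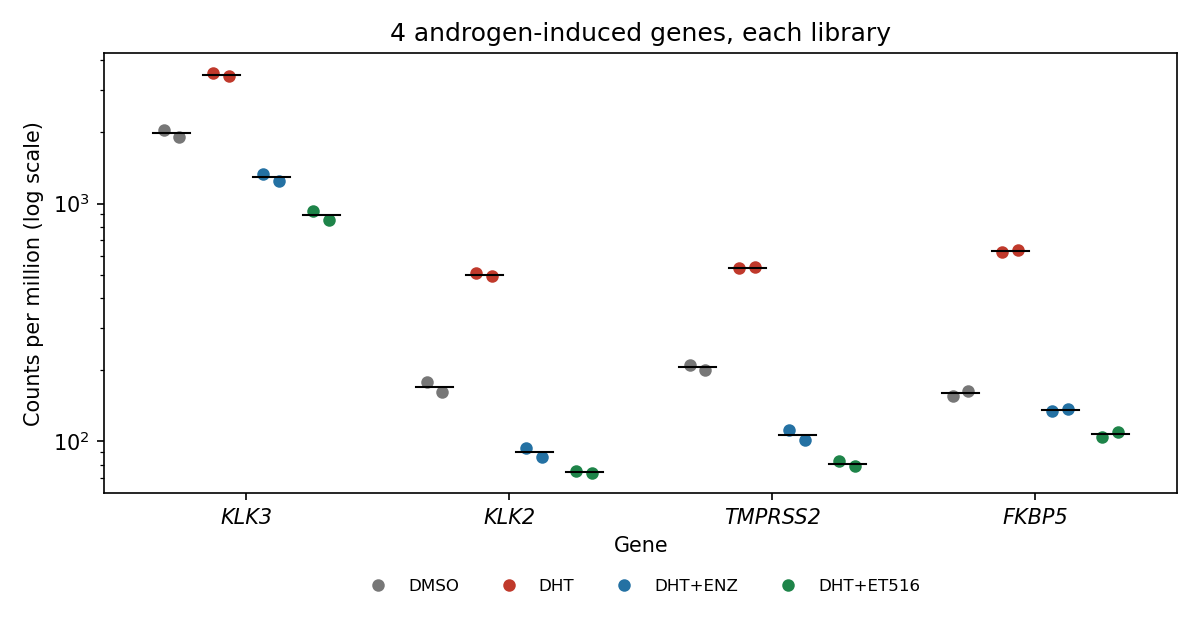
CPM (log axis) of 4 androgen-induced genes in each library, with 2 points per group and a bar at their mean. KLK3, KLK2, TMPRSS2 and FKBP5 were highest in DHT and lowest in DHT+ET516 (n = 2).

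The second comparison asked what ENZ did to DHT-treated cells. With ENZ, the androgen-induced genes that DHT had raised fell. KLK3 fell to 1290 ± 62 CPM (2.70-fold), KLK2 to 90.2 ± 5.3 (5.56-fold), TMPRSS2 to 107 ± 7.0 (5.02-fold) and FKBP5 to 135 ± 2.0 (4.65-fold; mean ± SD, n = 2, edgeR adjusted p of 1.02e-15 for KLK3 and 1.81e-28 or less for the other 3). Of 43 androgen-induced genes 38 fell, 1 rose and 4 did not pass, and adjusted over the list alone 39 fell and 1 rose. The median was -1.38, with an adjusted p of 5.44e-05 in camera with an estimated correlation. SLC2A3, a glucose transporter gene, had 66 counts over the DHT libraries and 0 over the DHT+ENZ libraries. It was at least 25.2-fold lower against a floor of 3 counts over the group. That bound takes the DHT counts as exact and does not cover the spread between samples. The median of the list was -1.38 with SLC2A3 at its bound.

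Among genes with a mean of at least 5 CPM over the 8 libraries, the largest decreases with ENZ were in MAF (-3.20 ± 0.20), RHOU (-3.12 ± 0.07), SGK1 (-3.00 ± 0.20), the prostate transporter gene SLC45A3 (-2.94 ± 0.06) and PMEPA1 (-2.83 ± 0.05). Among the same genes, the largest increases were in ACKR3 (1.70 ± 0.14), PLEKHS1 (1.66 ± 0.16), WNT5A (1.62 ± 0.18), SYTL2 (1.5 ± 0.08), the homeobox gene HOXA13 (1.41 ± 0.13) and MID1 (1.39 ± 0.18). Of 10 androgen-repressed genes 4 rose and none fell, over all genes and adjusted over the list alone. These were ACKR3, CAMK2N1 (0.66), FOLH1 (0.19) and UGT2B15 (0.46). The list's call (camera adjusted p = 0.0015) was lost with an estimated correlation (adjusted p = 0.103). The list passed fry (adjusted p = 0.0014), which does not compare its genes with other genes. UGT2B15 lost its call when any 1 of the 4 libraries was left out, with edgeR adjusted p of 0.098 and 0.1 without DHT replicates 1 and 2, and 0.136 and 0.0775 without DHT+ENZ replicates 1 and 2.

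Of 26 genes of the ATF4 integrated stress response, a programme for amino acid shortage and other stresses, 16 rose with ENZ and none fell, and adjusted over the list alone 18 rose. Examples were DDIT4, an inhibitor of mTORC1 signalling (0.76 ± 0.05), SESN2 (0.58 ± 0.06), TRIB3 (0.56 ± 0.05) and the cystine transporter gene SLC7A11 (0.38 ± 0.04). The median was 0.22, and the call (camera adjusted p = 4.46e-15) was lost with an estimated correlation (adjusted p = 0.0849). Against DMSO 14 of the 26 were higher with DHT+ENZ and 0 lower (adjusted over the list alone 21 higher), with a median of 0.20 and a camera adjusted p of 0.0119 with an estimated correlation. Of 19 unfolded protein response genes 8 fell and 1, XBP1, rose (0.28 ± 0.04), and adjusted over the list alone 11 fell and 1 rose. DNAJB9 (-0.79 ± 0.08), ERN1 (-0.58 ± 0.06) and HSPA5 (-0.23 ± 0.04) were among those that fell (camera adjusted p = 0.00049, and adjusted p = 0.089 with an estimated correlation). Of 17 fatty acid synthesis genes 5 fell, with ACSL3 at -1.16 and ELOVL5 at -1.02, and 4 rose, and adjusted over the list alone 6 fell and 5 rose. The median was 0.00, the mean -0.14 and the downward call (camera adjusted p = 1.35e-05) was lost with an estimated correlation (adjusted p = 0.106). Of 23 p53 targets 4 rose, among them BTG2 (0.69) and TP53INP1 (0.66), and 2 fell, among them the death receptor gene TNFRSF10B (-0.55). Adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 0.0204, and adjusted p = 0.117 with an estimated correlation). Of 5 aryl hydrocarbon receptor targets 3 fell, also adjusted over the list alone, with CYP1B1 at -1.20, TIPARP at -0.63 and CYP1A1 at -0.41 (camera adjusted p = 0.0115, and adjusted p = 0.117 with an estimated correlation). CYP1A1 lost its call in edgeR without DHT replicate 1 (adjusted p = 0.195), DHT+ENZ replicate 1 (0.308) or DHT+ENZ replicate 2 (0.0697). The other 13 lists did not pass.

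ENZ changed 1730 genes, 729 higher and 1001 lower, and 310 at least 2-fold. The count was 1087 without DHT+ENZ replicate 1 (446 higher and 641 lower) and 1078 without DHT+ENZ replicate 2 (458 higher and 620 lower), and without DHT replicate 1 the number higher was 458. Scaling by total counts only gave 1094 higher and 764 lower, 58.9% higher against 42.1%. Of the 655 genes that DHT raised, 574 fell with ENZ (87.6%, Wilson 95% interval 84.9 to 89.9), none rose and 81 did not pass, against 37.0 for independent lists. The Wilson intervals here and for ET516 treat genes as independent and do not cover the spread between libraries. Of the 429 genes that DHT lowered, 331 rose with ENZ (77.2%, interval 73.0 to 80.9) and 2 fell, against 17.6 and 24.2 for independent lists. Without DHT+ENZ replicate 1 the share of DHT-lowered genes that rose was 61.1%. Both comparisons use the same DHT libraries. Simulated unchanged groups gave at most 2 joint calls in 20 simulations. Few joint calls follow from that setting, so here and below such numbers do not show what shared libraries add among changed genes. The covariance of fold changes was -0.071 simulated and -0.175 observed (correlation -0.49 simulated and -0.66 observed). Part of the excess may come from the shared libraries.

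The third comparison asked the same of ET516. The androgen-induced genes fell here too. KLK3 fell to 892 ± 60 CPM (3.91-fold lower than DHT alone), KLK2 to 74.4 ± 1.1 (6.76-fold), TMPRSS2 to 80.7 ± 2.7 (6.65-fold) and FKBP5 to 107 ± 3.8 (5.88-fold; mean ± SD, n = 2, edgeR adjusted p of 1.09e-18 for KLK3 and 1.36e-29 or less for the other 3). Of the 43 androgen-induced genes 39 fell, 1 rose and 3 did not pass, and adjusted over the list alone 40 fell and 1 rose. The median was -1.71 (adjusted p = 0.000664 in camera with an estimated correlation). Of 10 androgen-repressed genes 5 rose and 3 fell, also adjusted over the list alone. That list had a median of -0.01, a mean of -0.04, an upward camera direction and an adjusted p of 0.867, and its median was 0.03 with total-count scaling.

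The ATF4, unfolded protein response, NRF2 and p53 lists were higher with ET516. Of 26 ATF4 list genes 24 rose and 1, ATF5, fell (-0.34), and adjusted over the list alone 25 rose and 1 fell, with a median of 1.26 (adjusted p = 0.00288 with an estimated correlation). DDIT3, which encodes the transcription factor CHOP (ENSG00000175197, chromosome 12, 57516588 to 57521737), rose from 20.4 ± 0.052 to 163 ± 11 CPM, 8-fold. TRIB3 rose to 484 ± 28 CPM (5.32-fold), SESN2 to 208 ± 6.5 (5.10-fold) and SLC7A11 to 1280 ± 1.4 (4.46-fold). Of 19 unfolded protein response genes 9 rose and 4 fell, and adjusted over the list alone 9 rose and 5 fell (median 0.15, adjusted p = 0.0221 with an estimated correlation). HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330) rose to 1620 ± 64 CPM (2.20-fold), ERN1 2.40-fold, XBP1 2.32-fold and HYOU1 1.81-fold. Of 16 NRF2 list genes 8 rose and 1 fell, and adjusted over the list alone 8 rose and 2 fell (median 0.11, mean 0.46, quartiles -0.05 and 0.57, adjusted p = 0.0238 with an estimated correlation). They included the heme oxygenase gene HMOX1 (5.93-fold), the glutathione synthesis gene GCLM (1.60-fold) and the ferritin heavy chain gene FTH1 (1.45-fold), and SLC7A11, which is a member of both this list and the ATF4 list. Of 23 p53 targets 14 rose and 2 fell, and adjusted over the list alone 15 rose and 3 fell (median 0.33, adjusted p = 0.0373 with an estimated correlation). GADD45A rose 4.12-fold and SESN1 2.12-fold.

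Besides the androgen-induced list, 5 lists passed camera as lower with ET516 with both the preset and an estimated correlation. These were DNA replication, MYC and ribosome biogenesis, fatty acid synthesis, cholesterol synthesis and heat shock. Of 35 DNA replication genes 28 fell and none rose, and adjusted over the list alone 29 fell (median -0.49, adjusted p = 0.0471 with an estimated correlation). UHRF1 (-1.23 ± 0.07), the flap endonuclease gene FEN1 (-1.12 ± 0.05), the helicase subunit gene MCM4 (-0.89 ± 0.04) and the ribonucleotide reductase subunit gene RRM2 (-0.73 ± 0.04) were among them. FEN1 overlaps FADS2 on the same strand of chromosome 11, so its counts are uncertain. Of 21 MYC and ribosome biogenesis genes 20 fell and 1 rose, also adjusted over the list alone (median -0.57, adjusted p = 0.0221 with an estimated correlation), including NOP56 (-1.14 ± 0.05), PPAN (-1.02 ± 0.07), NOP58 (-0.78 ± 0.05) and NCL, the nucleolin gene (-0.60 ± 0.04). Of 17 fatty acid synthesis genes 14 fell and 3 rose, also adjusted over the list alone (median -0.49, adjusted p = 0.0238 with an estimated correlation). FASN, which encodes fatty acid synthase (ENSG00000169710, chromosome 17, 82078333 to 82098332), fell from 2000 ± 67 to 613 ± 17 CPM, and SREBF1, a lipogenic transcription factor gene, fell by 0.96. Of 23 cholesterol genes 17 fell and 2 rose, also adjusted over the list alone, with INSIG1 at -0.76, LSS at -0.75 and HMGCS1 at -0.63 (adjusted p = 0.0374 with an estimated correlation). Of 18 heat shock genes 16 fell and 1 rose, also adjusted over the list alone (median -0.54, adjusted p = 0.0373 with an estimated correlation). HSPH1 (-0.94), DNAJA1 (-0.93) and HSPA8 (-0.64) fell. HSPA1B fell too (-1.94), but HSPA1A is a near-identical copy with a mean of 0.579 CPM in DHT, so the 2 cannot be separated by these counts.

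A further 4 lists passed with the preset correlation in this comparison and not with an estimated one. Of 28 mitosis genes 23 fell and 1, KIF2C, rose, also adjusted over the list alone, with CDK1 at -0.60 and the proliferation marker gene MKI67 at -0.52 (camera adjusted p = 0.000228, and adjusted p = 0.155 with an estimated correlation). Of 19 hypoxia genes 10 fell and 2 rose, and adjusted over the list alone 13 fell and 2 rose (camera adjusted p = 0.00132, and adjusted p = 0.286 with an estimated correlation). NDRG1 (-1.83), PFKFB3 (-1.27) and LDHA (-0.85) fell while VEGFA rose (0.87). NDRG1 is also a member of the androgen-induced list. Of 9 immediate early genes 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0185, and adjusted p = 0.129 with an estimated correlation). Those that rose included ATF3 (3.12), which is also a member of the ATF4 list, and JUN (1.36). Of 9 luminal identity genes 4 fell, with GRHL2 at -0.88, HOXB13 at -0.67 and GATA2 at -0.46, and 1, the E-cadherin gene CDH1, rose (0.52), also adjusted over the list alone (camera adjusted p = 0.0134, and adjusted p = 0.0957 with an estimated correlation). The other 6 lists did not pass.

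Among genes with a mean of at least 5 CPM over the 8 libraries, the largest increases with ET516 after DUX4L25 were in LAMP3 (log2 4.38 ± 0.20, from 1.29 ± 0.52 to 26.8 ± 0.28 CPM), the transcription factor gene BCL11B (4.08 ± 0.21), DBET, a noncoding transcript of the DUX4 repeat region (3.92 ± 0.22), the transglutaminase gene TGM1 (3.73 ± 0.17) and DMGDH (3.66 ± 0.23). DUX4L25, a copy in a repeat family whose counts are uncertain, stood at 20.3 ± 2.6 CPM against 0.578 ± 0.82 in DHT (n = 2, edgeR adjusted p = 0.0291). Its call was lost in DESeq2 (adjusted p = 0.271), limma-voom (0.0922), and edgeR with a replicate block (0.0582) or no filter (0.0575). It was also lost without any 1 of the DHT or DHT+ET516 libraries. There its log2 fold change ranged from 4.127 (without DHT replicate 1) to 11.412 (without DHT replicate 2). Among the same genes, the largest decreases were in SLC45A3 (-3.26 ± 0.06), SGK1 (-3.22 ± 0.21), the apelin gene APLN (-3.20 ± 0.17), the thrombospondin gene THBS1 (-3.04 ± 0.06) and the adrenergic receptor gene ADRA2A (-3.03 ± 0.15). ET516 changed 7961 of 17737 genes, 3778 higher and 4183 lower, and 1399 at least 2-fold (855 higher and 544 lower). Scaling by total counts only gave 4277 higher and 3632 lower, 54.1% higher against 47.5%. Of the 655 genes that DHT raised, 470 fell with ET516 (71.8%, Wilson 95% interval 68.2 to 75.1), 58 rose and 127 did not pass, against 154.5 lower and 139.5 higher for independent lists. Of the 429 that DHT lowered, 222 rose with ET516 (51.7%, interval 47.0 to 56.4) and 113 fell, against 91.4 and 101.2 for independent lists. Simulated unchanged groups gave at most 3 joint calls and a covariance of -0.072, against -0.161 observed. The correlation was -0.49 simulated and -0.41 observed, so it was no stronger than in unchanged groups. A correlation also weakens with the spread of the other changes by ET516, so this comparison alone decides nothing. Part of the joint calls may come from the shared DHT libraries.

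**Figure D2:**
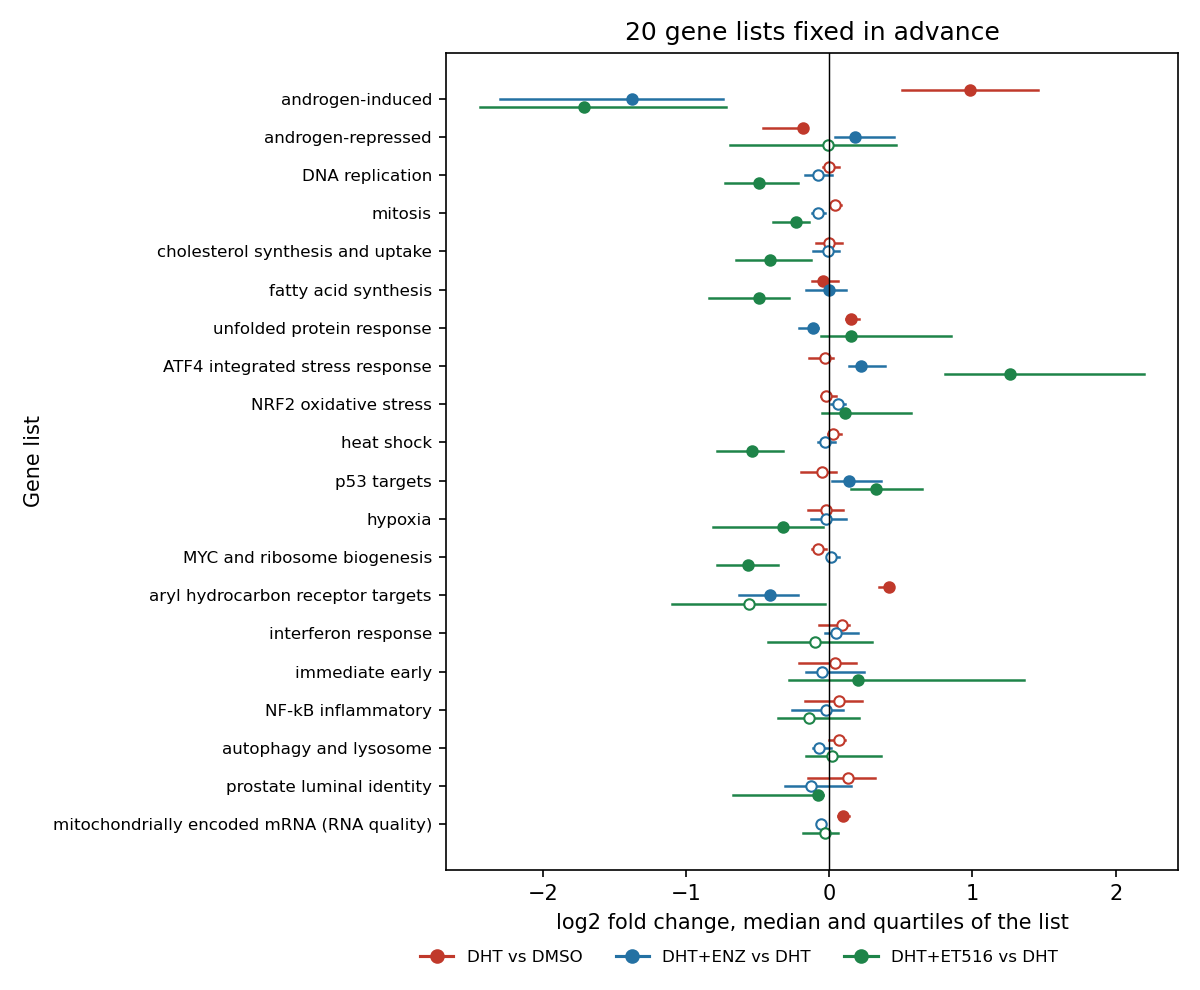
Median log2 fold change (points) and quartiles (lines) of the tested members of 20 gene lists, for DHT vs DMSO, DHT+ENZ vs DHT and DHT+ET516 vs DHT. Filled points passed camera at an adjusted p under 0.05 with the preset correlation, and the ATF4 list had medians of -0.03, 0.22 and 1.26.

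The compounds were also compared directly at the same concentration and time. The following 4 androgen-induced genes were lower with ET516 than with ENZ: KLK3 at -0.53 ± 0.05, TMPRSS2 at -0.41 ± 0.05, FKBP5 at -0.34 ± 0.05 and KLK2 at -0.28 ± 0.05 (log2 ± SE, edgeR adjusted p = 5.35e-05 or less). Over the 43 androgen-induced genes, 12 were higher with ET516, 16 lower and 15 did not pass, also adjusted over the list alone. The mean log2 level of the list differed by 0.01, with a 95% interval of -0.05 to 0.07. The median of the list was -0.03, or -0.04 without SLC2A3, which had at most 1 count in either group. The mean log2 fold change was 0.07, the direction in camera was down and its adjusted p was 0.247.

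Among genes with a mean of at least 5 CPM over the 8 libraries, the largest positive differences after DUX4L25 were in LAMP3 (3.82 ± 0.18), BCL11B (3.82 ± 0.19), TGM1 (3.59 ± 0.16) and the repeat-family members DUX4L26 (3.29 ± 0.12) and DBET (3.11 ± 0.19). DUX4L25 (4.90, edgeR adjusted p = 0.0303) lost its call in DESeq2 (adjusted p = 0.306) and limma-voom (0.0772). The same held in edgeR with a replicate block (0.0608), no filter (0.0597) or only the compared groups (0.0643). It was also lost without any 1 of the DHT+ENZ or DHT+ET516 libraries. There its log2 difference ranged from 3.754 (without DHT+ENZ replicate 1) to 11.419 (without DHT+ENZ replicate 2). Among the same genes, the largest negative differences were in ADRA2A (-3.35 ± 0.15), APLN (-2.82 ± 0.17), ACKR3 (-2.49 ± 0.16), the transcription factor gene SOX8 (-1.95 ± 0.20), the telomerase gene TERT (-1.94 ± 0.21) and the nestin gene NES (-1.93 ± 0.21).

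With ET516 against ENZ, 5 lists passed camera with both correlations. Of 26 ATF4 genes 24 were higher and 1 lower, also adjusted over the list alone, with DDIT3 at 2.46, TRIB3 at 1.85 and SLC7A11 at 1.78 (median 1.06, adjusted p = 0.00722 with an estimated correlation). Of 19 unfolded protein response genes 13 were higher and 1 lower, also adjusted over the list alone, with ERN1 at 1.84 and HSPA5 at 1.37 (median 0.24, adjusted p = 0.00783 with an estimated correlation). Of 16 NRF2 genes 8 were higher and 3 lower, and adjusted over the list alone 8 and 5, with HMOX1 at 2.26 (adjusted p = 0.035 with an estimated correlation). Of 18 heat shock genes 16 were lower and 1 higher, also adjusted over the list alone, with DNAJA1 at -0.79 and HSPH1 at -0.74 (adjusted p = 0.0424 with an estimated correlation). Of 21 MYC and ribosome biogenesis genes 18 were lower and 1 higher, and adjusted over the list alone 19 and 1, with RRS1 at -1.07 and NOP56 at -1.06 (adjusted p = 0.0206 with an estimated correlation).

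The other 9 lists that differed between the compounds with the preset correlation did not pass with an estimated one. In DNA replication 27 of 35 genes were lower with ET516, with MCM4 at -0.83 and FEN1 at -0.89 (adjusted over the list alone 27 lower and 1 higher, adjusted p = 0.0668 with an estimated correlation). In mitosis 15 of 28 were lower and 1, KIF2C, was higher (adjusted over the list alone 17 and 1, adjusted p = 0.223 with an estimated correlation). In cholesterol synthesis 17 of 23 were lower, with INSIG1 at -0.92, and 3 higher (adjusted over the list alone 18 and 3, adjusted p = 0.0668 with an estimated correlation). In fatty acid synthesis 11 of 17 were lower, with FASN at -1.54 and SREBF1 at -1.18, and 4 higher, also adjusted over the list alone (adjusted p = 0.0611 with an estimated correlation). Of 23 p53 targets 10 were higher, with GADD45A at 1.74, and 5 lower (adjusted over the list alone 11 and 6, adjusted p = 0.0746 with an estimated correlation). Of 19 hypoxia genes 11 were lower, with PFKFB3 at -1.38, and 2 higher, with VEGFA at 0.88, also adjusted over the list alone (adjusted p = 0.382 with an estimated correlation). Of 9 immediate early genes 4 were higher, with ATF3 at 2.88, and 2 lower, also adjusted over the list alone (adjusted p = 0.0746 with an estimated correlation). Of 15 autophagy and lysosome genes 6 were higher, with MAP1LC3B at 1.49 and GABARAPL1 at 0.94, and 3 lower, also adjusted over the list alone (adjusted p = 0.223 with an estimated correlation). Of 9 luminal identity genes 3 were lower, with GATA2 and HOXB13 both at -1.07, and 3 higher, with CDH1 at 0.37 (adjusted over the list alone 4 higher and 3 lower, adjusted p = 0.139 with an estimated correlation). That list had a median of 0.04, a mean of -0.16 and a downward camera direction.

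Between the compounds 7321 genes differed, 3615 higher and 3706 lower with ET516, and 1015 at least 2-fold. Against DHT, 1178 genes changed in the same direction with both compounds, 461 higher and 717 lower, against 155.3 and 236.1 for independent lists and at most 2 in simulated unchanged groups. The covariance of the fold changes was 0.221, against 0.072 simulated, and their correlation 0.54, against 0.51 simulated, and part of the excess may come from the shared DHT libraries. Without DHT+ENZ replicate 1 the number was 763, and without DHT+ENZ replicate 2 it was 775. A further 188 genes changed in opposite directions, 111 higher with ENZ and lower with ET516, and 77 the reverse, against 171.9 and 213.2 for independent lists, and the shared DHT libraries lower such calls by themselves. The direct difference passed in all 188, which is no added support, since opposite changes against the same libraries add up in it.

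**Figure D3:**
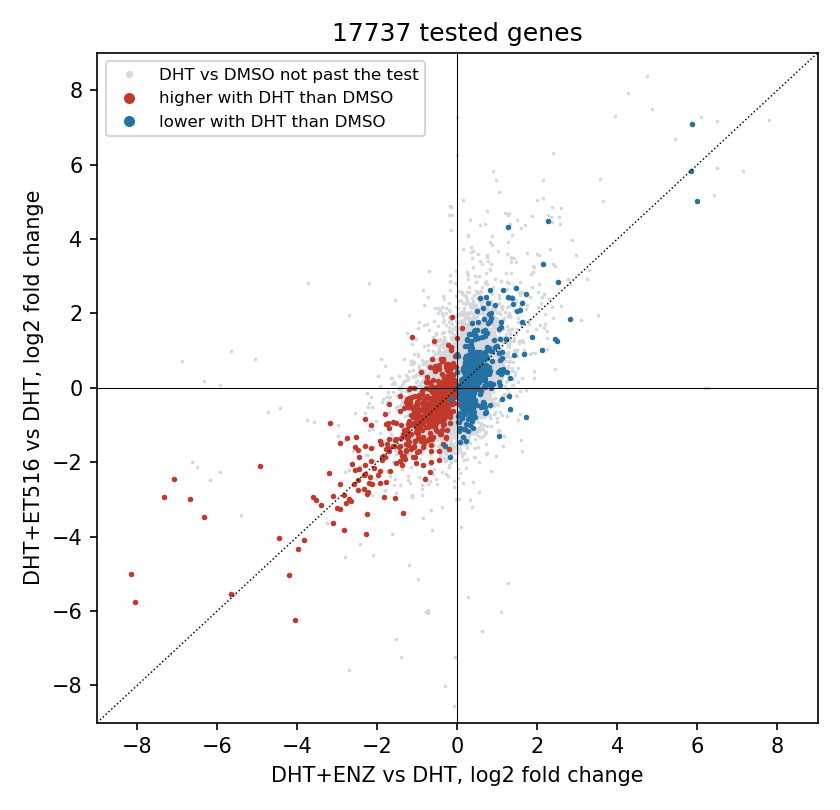
Log2 fold change against DHT with ENZ (horizontal) and with ET516 (vertical) for each of 17737 tested genes, coloured by the DHT vs DMSO result, with the dotted line at equal change; 4 genes lie outside the axes and the most extreme points are genes with few counts. Genes raised by DHT lie mostly in the lower left, and 574 of 655 passed as lower with ENZ and 470 of 655 with ET516.

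Against DMSO the question was what still set the compound-treated cells apart from cells without added DHT. With DHT+ENZ, KLK3 (-0.62 ± 0.05), KLK2 (-0.91 ± 0.05) and TMPRSS2 (-0.94 ± 0.05) were lower than in DMSO (log2 ± SE, edgeR adjusted p = 1.80e-08 or less). FKBP5 was lower by 0.24 ± 0.04 (edgeR adjusted p = 0.00138), and its call was lost without DMSO replicate 2 (adjusted p = 0.0809) or DHT+ENZ replicate 1 (adjusted p = 0.0803). With DHT+ET516, KLK3 (-1.15 ± 0.05), KLK2 (-1.19 ± 0.05), TMPRSS2 (-1.35 ± 0.05) and FKBP5 (-0.57 ± 0.05) were lower than in DMSO (edgeR adjusted p = 1.25e-12 or less). Of 43 androgen-induced genes, 26 were lower and 1 higher than in DMSO with ENZ (adjusted over the list alone 30 and 1), and 28 were lower and 4 higher with ET516 (adjusted over the list alone 30 and 4). In all, 233 genes differed from DMSO with DHT+ENZ (75 higher and 158 lower) and 7515 with DHT+ET516 (3745 higher and 3770 lower, or 3800 and 3717 when scaled by total counts only). The first count was 143 without DMSO replicate 2 (47 higher and 96 lower), 130 without DHT+ENZ replicate 1 (34 higher and 96 lower) and 103 without DHT+ENZ replicate 2 (28 higher and 75 lower). Of the lists, 8 passed with DHT+ENZ and 15 with DHT+ET516, and with an estimated correlation 2 (androgen-induced and ATF4) and 10.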

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

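Of the tests in this part, the comparison of ET516 with ENZ was planned, and the test of DHT-lowered genes against matched genes was chosen only after the result was seen. The results below stand out because the 2 compounds moved them in opposite directions against the same DHT libraries. The difference itself was also past the test in edgeR or camera. For genes that is no added support, since opposite changes against the same libraries add up in the difference.

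In all, 188 genes were called in opposite directions, 111 higher with ENZ and 77 higher with ET516, against 171.9 and 213.2 for independent lists. The shared DHT libraries lower such calls by themselves, so these numbers are not those of unchanged groups. Among the named genes, the unfolded protein response genes HSPA5 (ENZ -0.23, ET516 1.14, difference 1.37) and ERN1 (-0.58, 1.26, 1.84) fell with ENZ and rose with ET516, and so did the death receptor gene TNFRSF10B (-0.55, 0.44, 0.99). The unfolded protein response list differed by a median of 0.24, but its fall with ENZ (camera adjusted p = 0.00049) was lost with an estimated correlation (adjusted p = 0.089). The others rose with ENZ and fell with ET516: the prostate transcription factor genes GATA2 (0.61, -0.46, -1.07) and HOXB13 (0.39, -0.67, -1.07), the lipid genes SREBF1 (0.22, -0.96, -1.18) and SCD (0.12, -0.56, -0.68), and ACKR3 (1.70, -0.78, -2.49). So did ADRA2A (0.32, -3.03, -3.35), SOX8 (0.65, -1.30, -1.95), NES (0.60, -1.33, -1.93) and IER2 (0.26, -0.24, -0.50). For some of these genes the rise with ENZ was nearer the threshold, so the opposite direction is less certain. The edgeR adjusted p with ENZ was 0.0478 for ADRA2A, 0.0391 for SCD, 0.0306 for NES, 0.0246 for IER2 and 0.0103 for SOX8.

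Several of these, such as ACKR3, were lowered by DHT and lowered further with ET516, as were 113 of the 429 genes that DHT lowered. Whether ET516 lowered these as often as genes that DHT did not change was tested with 1 DHT library choosing the genes and the other compared with ET516, because a shared library shifts the shares. With DHT replicate 1 choosing 466 genes, 23.0% fell with ET516, against a mean of 27.5% (95% interval 23.4 to 31.5) over 1000 expression-matched draws, and with replicate 2 choosing 251 genes 20.7% fell, against 28.5% (23.1 to 33.9). In the same sets 43.3% rose, against 21% (17.2 to 24.7), and 49.0% rose, against 22.1% (17.1 to 27.5), which leaves fewer genes to fall, so an equally frequent lowering cannot be told apart from a rarer one. This test replaced one with shared DHT libraries, the rules of both were changed after their values were seen, and no biological explanation was tested.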

How the results depend on the processing

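Of the tests in this part, all were planned. In fits without 1 library, the lone sample of a group is assumed to vary like the other groups. Of 4176 refitted values of named genes, 4101 kept direction and call, 72 lost the call, 3 gained it and 0 reversed. The cause was not tested for any change below, except that a stricter threshold or a 2-fold minimum lowers a count by construction.

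DESeq2 called 697 genes in DHT vs DMSO (edgeR 1084), 1045 in DHT+ENZ vs DHT (1730) and 732 in the overlap of the compounds (1178). At an adjusted p under 0.01 there were 715, 1106 and, in DHT+ENZ vs DMSO, 147. At 2-fold or more the counts were 151, 310, 1399 (DHT+ET516 vs DHT), 1015 (DHT+ET516 vs DHT+ENZ), 20 (DHT+ENZ vs DMSO) and 1241 (DHT+ET516 vs DMSO). Without 1 library the counts ranged from 693 (without DMSO replicate 1) to 1071, 1078 (without DHT+ENZ replicate 2) to 1717, 6499 to 8013, 5801 to 7516, 103 (without DHT+ENZ replicate 2) to 283 and 6079 to 7663, in the order of the report, and the overlap from 763 (without DHT+ENZ replicate 1) to 1156.

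With an estimated correlation 3 of 6 lists passed camera in DHT vs DMSO, 1 of 7 in DHT+ENZ vs DHT, 10 of 14 in DHT+ET516 vs DHT and 5 of 14 in DHT+ET516 vs DHT+ENZ, 19 of 41 in all. The lists that lost the call this way passed fry (adjusted p = 0.0145 or less), except the mitochondrially encoded list with DHT (0.102). Fry asks whether the genes of a list changed, not whether they changed more than other genes. Passing it therefore does not restore a lost call. Lists that camera did not call passed it too, such as DNA replication with ENZ (fry adjusted p = 0.0302). With ET516 against DHT they included the interferon, NF-kB and aryl hydrocarbon receptor lists (fry adjusted p = 0.0433, 0.00997 and 0.0013). Several lost calls had an estimated correlation below the preset 0.01, so a higher correlation is not what lost them. These were the androgen-repressed (-0.051), unfolded protein response (-0.031), p53 (-0.003) and aryl hydrocarbon receptor (-0.04) lists with ENZ. The others were the aryl hydrocarbon receptor list with DHT (-0.051) and the luminal identity list with ET516 (-0.079). With ET516 against ENZ they were the p53 (-0.002) and luminal identity (-0.085) lists. The medians of the androgen-induced list kept direction and call under RLE and total-count scaling, both filters, the replicate block, thinning, an estimated correlation, fry and without 1 library, except that it passed as lower with ET516 than with ENZ in fry (-0.027, adjusted p = 0.0108) and not in camera (adjusted p = 0.247).

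The share of DHT-raised genes lower with ENZ (87.6%) was 90.6% with total counts, 83.1% with no filter, 90.9% with robust=FALSE, 91.5% with DESeq2, 91.4% with limma-voom and 93.3% with only the compared groups. Without 1 library it ranged from 81.9% to 91.9%, that of DHT-lowered genes higher with ENZ from 61.1% to 83.3%, that of DHT-raised genes lower with ET516 from 67.5% to 75.8% and that of DHT-lowered genes higher with ET516 from 46.8% to 55.0%.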

Other observations

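The ATF4 list and its test against DHT were planned. The tests of explanations, the other gene lists and the gene span values were chosen only after the result was seen.

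The ATF4 integrated stress response list rose with ET516, with a median of 1.26 against DHT alone. The choice among TMM, RLE and total-count scaling does not make the pattern, with a lowest median of 1.27 under RLE and total-count scaling. TMM factors spanned only 0.979 to 1.009, so a switch of scaling could hardly move the median, and other scaling errors were not tested. GC content and transcript length are argued against by a median of 1.17 after their trend was taken out (26 of 26 members, 1.5% of the variance over all genes). A single outlying library is argued against by a lowest median of 1.26 over fits without 1 of the DHT or DHT+ET516 libraries. Activation of this stress response by ET516 is a hypothesis that may account for the pattern, and no biological explanation was tested.

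Transcripts of the DUX4 repeat family were more abundant with ET516. Their summed counts were 117 and 139 CPM in the DHT+ET516 libraries and 13.2 to 20.4 CPM in the other 6, and 8 of the 12 tested members were higher than with DHT alone. Reads moved between copies are argued against by the sum, which was 5.77 times higher in the lowest DHT+ET516 library than in the highest of the others. The 20 genes that DUX4 switches on showed no rise as a sum. It was 1.67 and 2.33 CPM in the DHT+ET516 libraries and 1.52 to 2.53 CPM in the other 6, and the means differed 1.01-fold. Only 1 of the 20 had enough counts to test, so activity of the DUX4 protein cannot be told apart from its absence.

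Of 19 cytosolic aminoacyl-tRNA synthetase genes, 11 rose and 6 fell with ET516 against DHT (median 0.52, camera adjusted p = 7.37e-11, and 0.0154 as adjusted p with an estimated correlation), with GARS1 at 1.23 and SARS1 at 1.11. Of 17 mitochondrial ones 0 rose and 5 fell (median -0.08, camera adjusted p = 0.196). Of 15 amino acid transporter genes 9 rose, with SLC1A4 at 1.59, and 2 fell (median 0.45, camera adjusted p = 1.42e-05, and 0.0174 as adjusted p with an estimated correlation). Of 13 tubulin genes 10 fell, with TUBB4B at -0.97, and 1 rose (median -0.59, camera adjusted p = 4.53e-07, and 0.0154 as adjusted p with an estimated correlation), though their sequences are similar and single copies are uncertain. Of 26 snoRNA host genes 15 fell, with SNHG12 at -1.19, and 4 rose (median -0.39, camera adjusted p = 0.00391, and adjusted p = 0.239 with an estimated correlation).

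Of 24 HOX genes 6 fell with DHT (median -0.29, camera adjusted p = 4.59e-05, and 0.0461 as adjusted p with an estimated correlation) and 8 rose with ENZ (median 0.39, camera adjusted p = 7.68e-06, and 0.0348 as adjusted p with an estimated correlation). With ET516 5 rose, with HOXB9 at 2.11, and 3 fell, with HOXB13 at -0.67 (camera adjusted p = 0.517).

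Across 13324 protein-coding genes, the Spearman correlation of fold change with the span of the gene was 0.23 for ET516 against DHT, 0.26 for ET516 against ENZ, 0.01 for ENZ against DHT and -0.08 for DHT against DMSO. Between replicates it was -0.04 in DMSO, -0.21 in DHT, 0.09 in DHT+ENZ and 0.04 in DHT+ET516.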
